A study of Homo sapiens with 4 samples.

How the data were processed

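The data are 4 two-colour expression arrays of MDA-MB-231 cells, an established human breast cancer line. Per the labels' protocols, 2 sets of decoy and scrambled RNA were synthesised, transcribed in vitro, capped and poly-A tailed, and transfected with a lipid reagent at 80% confluency. Total RNA was taken 48 h later, and 200 ng per sample were labelled by linear amplification, with decoy in Cy3 and scrambled RNA in Cy5 on every array. Each set had 2 biological replicates, and the labels give no array with the dyes exchanged. The labels do not say how the RNA sequences of the sets differ.

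The scanner files hold, per spot and channel, a mean pixel intensity and a median local background intensity, and the authors obtained these with Agilent Feature Extraction 9.5.3.1, per the file headers (version 9 per the submitters' processing notes). The array design annotates its probes on genome build hg17, per the file headers, and coordinates were not used. The same files hold processed intensity values, background-subtracted and dye-normalized within the array, and a log10 ratio of red over green, per the file headers, besides flags for outlying, saturated and dim spots. The authors' deposited table gives a single log10 ratio of Cy3 over Cy5 for each of 20092 RefSeq accessions. It was pooled over arrays, and how arrays were combined is not stated. Its scale and direction were taken from the values, which followed the scanner files' log2 ratio of decoy over scrambled with a slope of 0.315 (r = 0.835 over 15120 accessions). It served as an alternative for named genes only.

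From the scanner files, mean spot signals were background-corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8) to read files. Ratios are log2 of decoy over scrambled. On set 2 replicate 1, 7 spots beside a bright speck, with a local background of up to 19366 in Cy3 and 14721 in Cy5, moved the fitted normexp background to -213 in Cy3 and -309 in Cy5, against -2.49 and -9.31 without them. Spots with a background-subtracted signal under -50 were therefore left out before normexp on all arrays, which touched only this array. That exclusion was decided after the counts with all spots had been seen and before any count with it. With all spots kept, 7565 genes passed over both sets against 9248, 6631 against 7154 in set 1, 3328 against 6529 in set 2, and 536 against 992 for the difference.

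Spots marked as outliers (147 to 215 per array) were left out. A probe was kept if it was well above background in either channel on at least 2 of 4 arrays, which held for 26716 of 41000 probes. Probes were named through the RefSeq table where their accession matched (17288 probes), otherwise by the symbol in the file. The probe of highest mean brightness stood for each of 20095 genes and other features, 11883 of them named through RefSeq, and 5049 had more than 1 probe. At least 1 array lacked a value for 108 features. Brightness is the mean log2 intensity over arrays and channels.

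A linear model in limma (lmFit and eBayes) had 1 coefficient per set over all 4 arrays, so that the sets shared an estimate of the spread, with 2 residual degrees of freedom and a prior of 3.03. Tested were the mean of the set effects, each set effect, and their difference, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, all two-sided. SE values are the moderated ones of this fit. All adjusted p values of genes come from limma. Agreement of the sets was given as Pearson and Spearman correlations across genes.

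The 23 gene lists, fixed before the data were examined, were interferon-stimulated genes, NF-kB inflammatory cytokines and chemokines, immediate-early response genes, hnRNP proteins, mRNA decay factors, mRNA stability RNA-binding proteins, mRNA splicing SR proteins, S phase and DNA replication, G2/M and mitosis, replication-dependent histones, p53 target genes, unfolded protein and integrated stress response, heat shock response, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, mesenchymal and invasion genes, TGF-beta response genes, extracellular matrix collagens and laminins, basal and luminal epithelial breast markers, leukocyte markers, and fibroblast and endothelial markers. Each list with at least 5 measured members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it.

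Named genes followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest called genes over both sets with the same sign on all 4 arrays, and the 6 highest and 6 lowest called genes in each set with the same sign on both of its arrays. For the difference it took the 6 highest and 6 lowest called genes. It added HNRNPA2B1 and, per list, the 4 members of smallest unadjusted p over both sets. Only features with a gene symbol, well above background in either channel, were named by size. A few genes that the rule or the lists would name are not reported here.

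The steps were tested on simulated arrays of 20095 genes. Changes were put into a small share of them, with independent noise per spot and no dye effect of single probes. Changes of 0.2, 0.4 and 0.8 on the log2 scale were recovered in 76.5%, 93.9% and 97% of cases over both sets, 55.2%, 85.1% and 97% in set 1, 38.2%, 75.8% and 90.9% in set 2, and 3.03%, 73.5% and 90.9% for the difference. Estimates came to 0.636 to 0.915 of the true size. Unchanged genes made up 10.9% of the calls over both sets, above the threshold of 0.05, 2.98% in set 1, 4.05% in set 2 and 1.75% for the difference. With the spots beside specks kept these shares were 2.68%, 0%, 4.44% and 1.89%, so a share above the threshold was seen only with those spots left out. A list of 25 members shifted by 0.15 was called at the preset correlation (adjusted p = 8.14e-45) but not with an estimated one (adjusted p = 0.198), and 0 of 50 random lists were called.

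Alternatives chosen before the data were examined were no background correction, the scanner software's log ratio, median centring in place of loess, quantile normalization of brightness between arrays, no filter and a stricter filter on dim probes, the mean of a gene's probes, outlying spots kept, a prior following intensity, 1 coefficient for all arrays, the set as a random block, the replicate number as a block, each array left out, the authors' deposited table and an estimated correlation. Loess within bins of probe GC content and keeping the spots beside specks were added after the data had been seen. The bounds of 70% GC and a brightness of 13 for bright high-GC probes were set after the named genes had been seen.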

Results

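Gene expression was measured in MDA-MB-231, an established human breast cancer line, 48 h after transfection of synthetic RNA. Cells received a decoy RNA made for sRSM1, a structural RNA element of messenger RNAs, or a scrambled RNA. The element is known as a binding site of HNRNPA2B1, an RNA-binding protein, and the question was which transcripts differ when extra copies of the element are present. Decoy and scrambled RNA came as 2 pairs, set 1 and set 2, each used in 2 biological replicates, for 4 arrays in all. Every array carried the decoy sample in Cy3 and the scrambled sample in Cy5, so a dye effect that is constant for a gene was part of each ratio and dropped out in the difference between the sets. The median signal per array ran from 48.7 to 60.1 in Cy3 over a median background of 22.5 to 24.5, and from 117 to 184 in Cy5 over 47 to 52. Between 57.3% and 62.5% of the 43376 probe spots were well above background in Cy3 and between 62.3% and 66.7% in Cy5, and 0 spots were saturated. The number of arrays limited the precision, with a median SE of 0.020 on the log2 scale over both sets and 0.028 within a set. The offset of 50 lay above the median Cy3 signal after background correction (28 to 40 per array). Such an offset draws ratios of dim probes, and their SE, towards 0. On simulated arrays estimates came to 0.636 to 0.915 of the true size.

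The first comparison asked which transcripts differed between decoy and scrambled RNA over both sets. STT3A, a catalytic subunit of the oligosaccharyltransferase, was the highest named transcript, at a log2 ratio of 0.60 ± 0.017 (SE, n = 4 arrays; 1.52-fold; RefSeq NM_152713). It was followed by IPO7, a nuclear import receptor (0.52 ± 0.017), and by BBC3, a promoter of apoptosis (0.51 ± 0.022). DKK1, a secreted inhibitor of Wnt signalling, was the lowest at -0.48 ± 0.017 (RefSeq NM_012242), before PNMA2 (-0.47 ± 0.021) and DLGAP4 (-0.47 ± 0.020). Set 2 carried most of the 2 extremes, with STT3A at 0.24 in set 1 and 0.96 in set 2 and DKK1 at -0.13 and -0.84. The SE covers only the spread of arrays within a set. The values are read against the within-array loess curve. With median centring in its place, the median of all genes moved from -0.016 to -0.54, and ratios fell with brightness (correlation -0.87). All 12 of the highest genes then lay below 0, while the 12 lowest stayed below 0. STT3A (-0.24), IPO7 (-0.22), TAF15 (-0.39), CDH24 (-0.49), BBC3 (-0.50), FOXQ1 (-0.51) and CDC42EP5 (-0.52) still lay above that median. BMP8A, PARP10, HCN4, HES7 and PKN2 lay below it. Here and below, a value below 0 with median centring therefore shows neither a reversal relative to other genes nor, for lower genes, a stable result.

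The other transcripts of the highest 12 were CDC42EP5 (0.50 ± 0.024), CDH24 (0.49 ± 0.016), HCN4 (0.48 ± 0.017), BMP8A (0.47 ± 0.018), HES7 (0.47 ± 0.017) and FOXQ1 (0.47 ± 0.018), then TAF15 (0.47 ± 0.017), PKN2 (0.46 ± 0.016) and PARP10 (0.46 ± 0.023), all with the same sign on 4 of 4 arrays and below 0 with median centring. TAF15 is an RNA-binding protein of the FET family, HES7 a transcriptional repressor and FOXQ1 a forkhead transcription factor. Of these 12 genes, 9 were read by bright probes with a GC content of at least 70%, all but STT3A, IPO7 and TAF15. Among all 69 probes at or above that GC content and a mean log2 brightness of 13, 68 had a ratio above 0.2 and the median was 0.44, against 64 of 1512 equally bright probes of lower GC content. After loess within bins of probe GC the median of these probes was 0.079. These bounds were chosen after the named genes had been seen. Where these genes had other probes past the filter, those gave lower values, as for BBC3 (-0.083 and -0.047), CDH24 (-0.16), FOXQ1 (0.051), IPO7 (0.070) and TAF15 (0.014), and PKN2 ranged from -0.022 to 0.046.

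The remaining lowest transcripts were DHTKD1 (-0.44 ± 0.018), NANOS1 (-0.44 ± 0.016), FAM241A (-0.43 ± 0.018), POLR2L (-0.42 ± 0.017) and NNMT (-0.41 ± 0.017), then KITLG (-0.41 ± 0.016), RPL6 (-0.40 ± 0.028), ABCA1 (-0.38 ± 0.021) and APOLD1 (-0.38 ± 0.020), each with the same sign on 4 of 4 arrays. NNMT methylates nicotinamide, KITLG is stem cell factor, ABCA1 exports cholesterol, NANOS1 is an RNA-binding repressor of translation, and POLR2L and RPL6 are subunits of an RNA polymerase and of the ribosome. Adjusted p ran from 0.000562 to 0.00128 over the 24 genes. DLGAP4 lay at 0.23 with the scanner software's own ratio, and its other probe gave 0.19. DHTKD1 (0.030), KITLG (0.025), RPL6 (0.12) and FAM241A (-0.0093) also had a second probe with a value away from the brightest one. The same held for the 2 other probes each of POLR2L (-0.10 and 0.13) and ABCA1 (-0.076 and -0.049). PNMA2, DLGAP4, DHTKD1, FAM241A, POLR2L and RPL6 lay above 0 in the authors' deposited table. The median of that table was itself above 0 (0.0134 on the log10 scale), and PNMA2 (0.013) and FAM241A (0.006) lay below it. HNRNPA2B1 itself was at 0.074 ± 0.016 (adjusted p = 0.0165), with 0.12 ± 0.022 in set 1 and 0.027 ± 0.022 in set 2 (adjusted p = 0.402), and it lay at -0.90 over both sets with median centring.

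**Figure D1:**
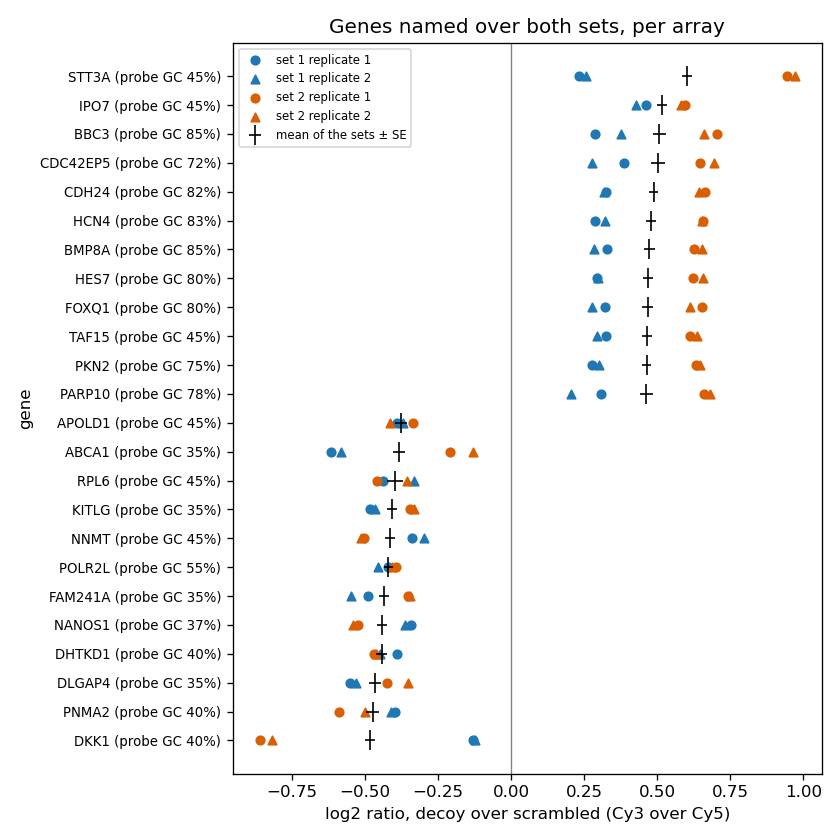
Log2 ratio of decoy over scrambled RNA (x axis) for the 12 highest and 12 lowest named genes over both sets (y axis, with the GC content of the probe), as points for the 4 arrays and crosses for the mean of the sets with its SE. STT3A lies at 0.96 in set 2 and 0.24 in set 1, DKK1 at -0.84 and -0.13. With median centring in place of loess the 12 highest genes lie below 0, as does the median of all genes (-0.54).

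In all, 9248 of 20093 genes passed an adjusted p of 0.05 over both sets (limma), 3788 higher and 5460 lower with the decoy, and 11014 had an unadjusted p under 0.05. The median size of a called change was 0.12 on the log2 scale. With median centring 18953 genes passed, 22.8% of them higher against 41% with loess (49.1% with the scanner software's ratio, 49.9% with loess within bins of probe GC), and with the set as a random block 3289 passed (6020 with 1 coefficient for all 4 arrays). On simulated arrays the same steps recovered 76.5% of changes of 0.2 and 93.9% of changes of 0.4, but 10.9% of the calls over both sets were unchanged genes (20 of 19870 such genes). Those arrays held few changed genes, independent noise and no dye effect of single probes. Their shares therefore do not carry over to the 9248 calls here.

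Of the 23 gene lists, the replication-dependent histones, which package newly made DNA, stood apart over both sets, with 16 higher and 1 lower of 25 measured members and a median of 0.11 (17 and 1 adjusted over the list alone). Camera gave an adjusted p = 2.94e-05 for them, an adjusted p = 0.687 with an estimated correlation, and the opposite direction with median centring (adjusted p = 0.196). Members included H4C2 (0.25 ± 0.019), H3C7 (0.18 ± 0.016), H2AC18 (0.22 ± 0.020) and H1-4 (0.21 ± 0.019), all below 0 with median centring. No other list passed over both sets (adjusted p = 0.064 to 0.995), and 0 of 23 passed with an estimated correlation, where 0 had an unadjusted p under 0.05. Camera with an estimated correlation also missed a simulated list whose members were all shifted by 0.15 (adjusted p = 0.198). Here and below, a list that does not pass it is therefore not shown to be unchanged. Fry, which asks whether members move on balance one way without comparing them with other genes, called 16 of 23. SE of the list members named here and below was 0.016 to 0.029 (n = 4), and 0.035 for THY1. Other probes of list members, where not given beside them, lay at 0.0056 for H2AC18, 0.065 for TRIB3, 0.18 for XBP1, -0.0025 for HMGCS1, 0.0013 for MVK, 0.049 for SDHA, and -0.059 for RFC3. They lay at -0.033 for CENPF, -0.075 for CKAP2, -0.082 for RPL18, -0.074 for LAMA3, 0.14 (2 probes) for SRRM1, -0.36 to -0.083 for CNOT7 and -0.095 to 0.090 for RPL7A. Counts adjusted over the list alone are given where they differed from those over all genes. As a baseline for the list counts, 3788 of all 20093 genes were higher and 5460 lower over both sets. A count near these shares shows nothing particular to its list.

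Among interferon-stimulated genes, the antiviral response, 16 were higher and 7 lower of 44 (median 0.030, adjusted p = 0.064). The members ISG20 (0.33), IFIT3 (0.30), DHX58 (0.28) and OASL (0.24) were higher, and below 0 with median centring. NF-kB cytokines and chemokines had 8 higher and 10 lower of 29 (median -0.028), with TNFSF10 (-0.24), the NF-kB inhibitor NFKBIA (-0.25), TNFAIP2 (-0.30) and IL6 (-0.18) lower. Immediate-early genes, which respond to growth signals within minutes, had 8 higher and 12 lower of 28 (median -0.032). CCN1 was lower on each of 3 probes (-0.30, -0.22 and -0.20), as were DUSP1 (-0.25), JUND (-0.25) and JUNB (-0.20), whose other probe gave 0.072 and which lay at 0.19 in the authors' deposited table.

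RNA-binding proteins went both ways. For hnRNP proteins, the family of HNRNPA2B1, 7 were higher and 8 lower of 24 (median -0.013, camera direction upwards). HNRNPH2 (-0.35) and HNRNPF (-0.17) were lower, while HNRNPAB (0.20) and HNRNPL (0.18, other probes 0.17 and 0.20) were higher with loess and below 0 with median centring. mRNA decay factors had 5 higher and 13 lower of 50 (5 and 12 adjusted over the list alone, median -0.0022), among them the deadenylase subunits CNOT7 (-0.23) and CNOT6L (-0.26, other probe 0.0048), LSM6 (-0.26) and the exosome subunit EXOSC9 (-0.21). RNA-binding proteins that control mRNA stability had 11 higher and 12 lower of 35 (11 and 15 adjusted over the list alone, median -0.027). ZC3H12A, an endonuclease that degrades inflammatory mRNAs, was at -0.30 and PUM2 at -0.23 (other probes -0.12 and 0.036, 0.084 in the authors' deposited table), and CELF1 was at 0.29, or -0.21 with median centring. SR splicing proteins had 3 higher and 9 lower of 21 (median -0.028): SRSF2 (-0.31) and SRSF11 (-0.17) were lower, and SRSF1 (0.19, other probe -0.058) and SRRM1 (0.16) were higher with loess and below 0 with median centring.

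Of the other cell cycle lists, G2/M and mitosis genes had 5 higher and 18 lower of 36 (median -0.058, adjusted p = 0.181), with HMMR (-0.27), ASPM (-0.25), CENPF (-0.23) and CKAP2 (-0.24) lower. Of these, ASPM (0.063) and CENPF (0.034) lay above 0 in the authors' deposited table, CENPF below that table's median, and the other probe of ASPM gave 0.049. S phase and DNA replication genes had 9 higher and 10 lower of 35 (median -0.0034, camera direction upwards), and RFC3 (-0.20), PCNA (-0.16), TYMS (-0.19) and POLA1 (-0.17) were lower. p53 targets had 9 higher and 6 lower of 24 (median 0.026). BBC3 and the pro-apoptotic PHLDA3 (0.26) and AEN (0.16) were higher with loess and below 0 with median centring, and CCNG1 (-0.12) was lower.

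Stress and metabolic lists were mixed. The unfolded protein and integrated stress response had 11 higher and 7 lower of 31 (12 and 9 adjusted over the list alone, median 0.021). Its members TRIB3 (0.34), PDIA4 (0.29), XBP1 (0.22) and HERPUD1 (0.16) were higher with loess and below 0 with median centring. Heat shock genes had 7 higher and 3 lower of 21 (median 0.015). The chaperones HSPD1 (-0.14) and HSP90AA1 (-0.14) were lower, the latter at 0.047 as the mean of its probes and both above 0 in the authors' deposited table (0.078 and 0.14) and on other probes (0.038, and 0.049 to 0.17), HSPA6 (0.12) was higher, and DNAJA1 (0.13, other probe -0.11) was higher with loess and below 0 with median centring. Cholesterol biosynthesis had 7 higher and 6 lower of 24 (median 0.024, mean -0.0055), with HMGCS1 (-0.23), DHCR7 (-0.19) and STARD4 (-0.19) lower, HMGCS1 lying at 0.086 in the authors' deposited table, and MVK (0.19) higher, or below 0 with median centring. Glycolysis and hypoxia genes had 11 higher and 10 lower of 30 (median 0.0072): LOX (-0.20), BNIP3 (-0.20) and SLC2A1 (-0.19) were lower, and VEGFA was at 0.30 (other probes -0.025 to 0.097), or -0.39 with median centring. Oxidative phosphorylation had 7 higher and 5 lower of 30 (median 0.024), with ATP5F1A (-0.17) lower and SDHA (0.20) and COX6C (0.13) higher with loess and below 0 with median centring. Cytosolic ribosomal proteins had 6 higher and 22 lower of 43 (8 and 24 adjusted over the list alone, median -0.084, adjusted p = 0.142), from RPL6 (-0.40) and RPL7A (-0.27), at 0.13 and 0.12 in the authors' deposited table, and RPL18 (-0.26) to RPS23 (0.20), which lay at -0.76 with median centring.

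Lists for cell identity and invasion were likewise uncalled. Mesenchymal and invasion genes had 6 higher and 9 lower of 31 (median -0.013, camera direction upwards). The matrix protease MMP14 (0.28) and the fibronectin receptor subunit ITGA5 (0.21) were higher with loess and below 0 with median centring, and CDH11 (-0.18) and LOXL2 (-0.14) were lower. TGF-beta response genes had 6 higher and 6 lower of 23 (median -0.0057, camera direction upwards), with INHBA (-0.19) and CCN2 (-0.14) lower and ANGPTL4 at 0.15, or -0.22 with median centring. Collagens and laminins had 3 higher and 9 lower of 19 (3 and 11 adjusted over the list alone, median -0.071, camera adjusted p = 0.259). LAMA3 (-0.35), COL4A1 (-0.29), COL8A1 (-0.28) and FBN1 (-0.25) were lower. However, LAMA3 (0.041) and COL4A1 (0.29) lay above 0 in the authors' deposited table, LAMA3 below that table's median. Epithelial breast markers had 5 higher and 9 lower of 22 (median -0.042), with CDH1 (-0.21) and KRT7 (-0.099) lower and KRT19 at 0.19, or -0.79 with median centring. Leukocyte markers had 2 higher and 1 lower of 10 (median -0.040), with CSF1R at 0.18 (-0.58 with median centring), TYROBP at 0.091, CD79A at -0.13 and CD8A at -0.085 (not past the threshold). Fibroblast and endothelial markers had 1 higher and 1 lower of 10 (0 and 1 adjusted over the list alone, median -0.034). PDGFRB was at -0.27, THY1 at 0.12 (-0.66 with median centring), and COL1A2 (-0.049) and PECAM1 (0.081) were not past the threshold.

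The second comparison took set 1 alone. FLNA, an actin crosslinker, was the highest named transcript at 0.56 ± 0.023 (SE, n = 2 arrays; 1.47-fold), followed by CHPF, a chondroitin synthesis factor (0.46 ± 0.053), FKBP1A, an immunophilin (0.45 ± 0.023), IPO7 (0.44 ± 0.024), the Hippo pathway kinase LATS2 (0.44 ± 0.023) and HDGF (0.43 ± 0.023). With median centring all of these but CHPF lay below 0. The lowest were the cholesterol exporter ABCA1 (-0.60 ± 0.029), ZNF518A (-0.60 ± 0.171), the peptide hormone EDN2 (-0.55 ± 0.038), DLGAP4 (-0.54 ± 0.028) and FAM241A (-0.52 ± 0.026) and the complement regulator CD46 (-0.52 ± 0.031), and DLGAP4 lay at 0.34 with the scanner software's ratio. Adjusted p was 0.00461 to 0.00609 for these genes but 0.0493 for ZNF518A. The latter lay at -0.98 on replicate 1 and -0.22 on replicate 2 and had another probe at -0.032 over both sets. The other probes of FKBP1A ran from -0.14 to 0.21 over both sets. Histones were again the called list, with 17 higher and 0 lower of 25 (20 and 1 adjusted over the list alone), a median of 0.13 and an adjusted p = 1.37e-07, which was an adjusted p = 0.641 with an estimated correlation and turned downwards with median centring. H1-4 was at 0.33 ± 0.028 and H3C7 at 0.32 ± 0.023. By limma, 7154 of 20094 genes passed, 2799 higher and 4355 lower, with 9615 at an unadjusted p under 0.05. The count was 3487 with the scanner software's ratio, 4484 without the filter on dim probes, 18683 with median centring (22.2% higher against 39.1%), and 0 without either array of the set, where 6642 and 6886 genes had an unadjusted p under 0.05.

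The third comparison took set 2 alone. STT3A was 1.94-fold higher with the decoy (0.96 ± 0.024; SE, n = 2 arrays), and HS2ST1, a heparan sulfate sulfotransferase, followed at 0.69 ± 0.027. BBC3 (0.68 ± 0.031), PARP10 (0.67 ± 0.032) and CDC42EP5 (0.67 ± 0.034) and the CREB coactivator CRTC1 (0.66 ± 0.029) came next, and all 6 but STT3A were read by bright probes with a GC content of at least 70% and lay below 0 with median centring. The other probes of HS2ST1 ran from -0.13 to 0.057 over both sets. DKK1 was the lowest at -0.84 ± 0.024 (0.559-fold), with PNMA2 (-0.55 ± 0.030) and NANOS1 (-0.53 ± 0.023), the glucocorticoid-regulated kinase SGK1 (-0.51 ± 0.028) and NNMT (-0.51 ± 0.024) and DHTKD1 (-0.47 ± 0.026), and each of the 12 had the same sign on both arrays of the set (adjusted p = 0.00071 to 0.00121). Interferon-stimulated genes were higher as a group, with 21 higher and 3 lower of 44 (22 and 3 adjusted over the list alone) and a median of 0.11. Their adjusted p = 3.24e-05 became an adjusted p = 0.461 with an estimated correlation, and the direction turned with median centring (adjusted p = 0.285). ISG20 (0.42 ± 0.024), DHX58 (0.39 ± 0.022) and IFIT3 (0.33 ± 0.023) were among them. G2/M and mitosis genes were lower, with 3 higher and 20 lower of 36 and a median of -0.11 (adjusted p = 0.0105, and adjusted p = 0.461 with an estimated correlation), as for HMMR (-0.24 ± 0.023) and CKAP2 (-0.22 ± 0.030). The histones were not called in set 2, with 6 higher and 3 lower of 25 and a median of 0.053 (camera adjusted p = 0.0693). By limma, 6529 of 20094 genes passed, 2927 higher and 3602 lower, with 9053 at an unadjusted p under 0.05. The count was 4066 with the scanner software's ratio, 3960 without the filter on dim probes, 18047 with median centring (21.7% higher against 44.8%), 3328 with 7 spots beside a bright speck kept (30.5% higher), and 1290 and 1613 without replicate 1 or replicate 2 of the set.

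The fourth comparison, set 1 minus set 2, asked whether the decoy pairs differed in effect. A constant dye effect cancels in it, but a probe or dye effect that varies between the sets does not. DKK1 was 0.71 ± 0.034 higher on the log2 scale in set 1 than in set 2 (SE, 2 arrays per set), and STT3A lay at -0.71 ± 0.034. The desaturase SCD was at -0.46 in set 1 and 0.23 in set 2 (difference -0.69 ± 0.050), and SREBF1, a transcription factor for lipid genes, at -0.32 and 0.22 (difference -0.54 ± 0.035). Also higher in set 1 were GNAZ (0.65 ± 0.051), PAX4 (0.60 ± 0.062) and CTSZ (0.58 ± 0.052), then SGK1 (0.53 ± 0.039) and TRAM2 (0.52 ± 0.033). HLA-DPB1 (-0.56 ± 0.035), the neurotrophin receptor NGFR (-0.52 ± 0.047) and UTS2R (-0.50 ± 0.032) were lower in set 1 than in set 2. The probe of UTS2R is bright with a GC content of 73.3%, and the 68 called genes with such probes were all among those lower in set 1 than in set 2. Bright probes with a GC content of at least 70% had a median of 0.26 in set 1 and 0.625 in set 2, so their shared shift did not cancel. Adjusted p was 0.0216 for DKK1 and STT3A and 0.023 for the other 10 genes. HNRNPA2B1 was 0.095 ± 0.032 (adjusted p = 0.133).

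Of the 23 lists, 11 differed between the sets with camera. With an estimated correlation none passed (adjusted p = 0.471 for ribosomal proteins, 0.228 for glycolysis and hypoxia, 0.205 for the other 9), and 4 had an unadjusted p under 0.05. That setting also missed a simulated shifted list over both sets, so not passing it decides nothing for these lists. The list members named next were chosen after their values had been seen, as up to 3 per list with the largest called difference. Lower in set 1 than in set 2 were interferon-stimulated genes (0 higher and 10 lower of 44, or 1 and 18 adjusted over the list alone; median -0.13; adjusted p = 3.68e-05), such as MX1 (-0.49), IFI44L (-0.40) and IFI44 (-0.34). NF-kB cytokines and chemokines had 0 higher and 7 lower of 29 (1 and 15 adjusted over the list alone) and a median of -0.16 (adjusted p = 0.000178), with the interferon IFNL1 (-0.47), IL1B (-0.35) and NFKBIA (-0.28). Cholesterol biosynthesis had 0 higher and 4 lower of 24 (0 and 13 adjusted over the list alone), a median of -0.14 (adjusted p = 0.000178), and STARD4 (-0.30) and INSIG1 (-0.21), while DHCR7 was lower in both sets (-0.27 and -0.12). Glycolysis and hypoxia genes had 0 higher and 1 lower of 30, BNIP3 (-0.29), or 3 and 11 adjusted over the list alone, with a median of -0.083 (adjusted p = 0.0204). Cytosolic ribosomal proteins had 1 higher and 1 lower of 43, RPL13 (-0.18) being the lower, or 1 and 9 adjusted over the list alone, with a median of -0.059 (adjusted p = 0.0108), which did not pass with the scanner software's ratio (adjusted p = 0.374).

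Higher in set 1 than in set 2 were the histones (5 higher and 0 lower of 25, or 6 and 1 adjusted over the list alone; median 0.096; adjusted p = 3.68e-05), which turned downwards with median centring, such as H3C2 (0.43), H2AC4 (0.32) and H3C7 (0.26). Mesenchymal and invasion genes had 5 higher and 1 lower of 31 (10 and 1 adjusted over the list alone), a median of 0.059 (adjusted p = 0.000627), and THBS1 (0.49) and TGFBI (0.27) among the higher. TGF-beta response genes had 3 higher and 1 lower of 23 (5 and 1 adjusted over the list alone) and a median of 0.085 (adjusted p = 0.00137), with CCN2 (0.49) besides TGFBI, which both lists hold. hnRNP proteins had 2 higher and 0 lower of 24, HNRNPA0 (0.42) and HNRNPUL1 (0.31), with a median of 0.061 (adjusted p = 0.00564). Stability RNA-binding proteins had 3 higher and 1 lower of 35 (7 and 1 adjusted over the list alone) and a median of 0.034 (adjusted p = 0.0108), with YBX1 (0.32), IGF2BP2 (0.31) and RBMS1 (0.21) higher. G2/M and mitosis genes had 5 higher and 0 lower of 36 (6 and 0 adjusted over the list alone) and a median of 0.0485 (adjusted p = 0.0108), with BUB1B (0.24), ANLN (0.23) and CDC20 (0.19). The hnRNP, stability and G2/M lists turned downwards with median centring, and the mesenchymal list no longer passed (adjusted p = 0.146).

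**Figure D2:**
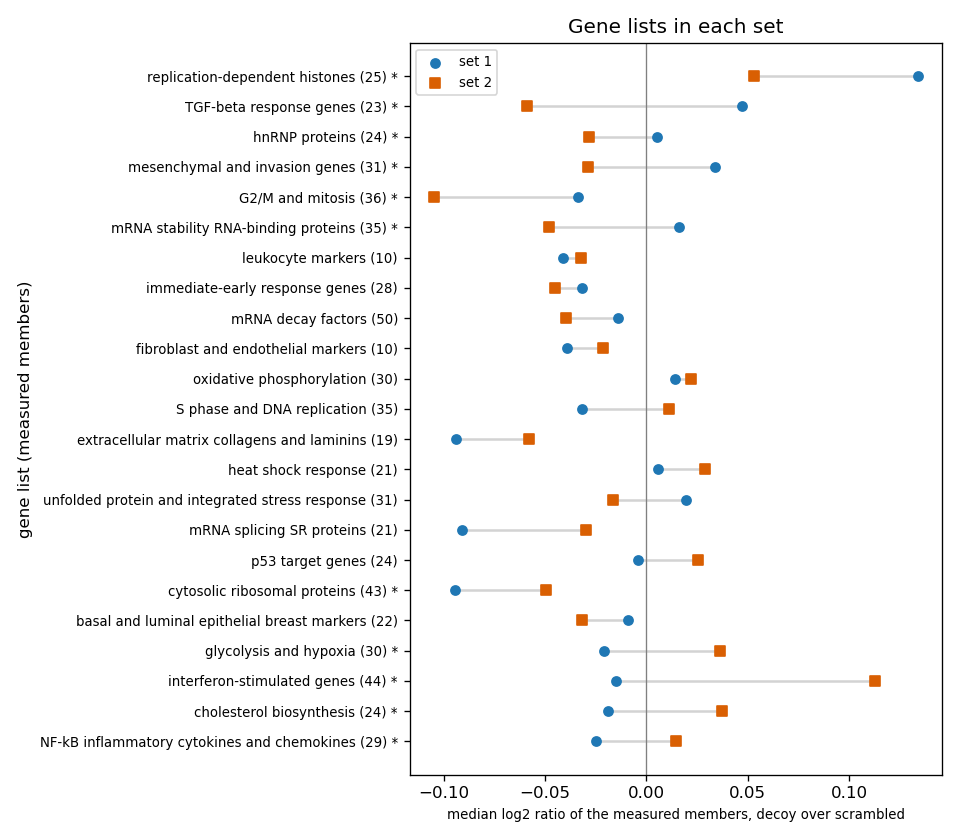
Median log2 ratio of decoy over scrambled RNA over the measured members (x axis) of each of the 23 gene lists (y axis, members in brackets), as circles for set 1 and squares for set 2, with * for lists whose difference between the sets had a camera adjusted p under 0.05. Interferon-stimulated genes lie at -0.015 in set 1 and 0.11 in set 2 and histones at 0.13 and 0.053, and with median centring in place of loess the difference turns for histones, hnRNP proteins, stability RNA-binding proteins and G2/M genes, as does the called direction of histones in set 1 and of interferon-stimulated genes in set 2.

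By limma, 992 of 20093 genes differed between the sets, 391 higher and 601 lower in set 1, with 5703 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0216. This count was 536 with 7 spots beside a bright speck kept (53.2% higher against 39.4%), 8787 with median centring (19.8% higher), 2076 with a stricter filter, 4663 with a prior following intensity, and 0 with the scanner software's ratio or without a filter (4809 and 5819 at an unadjusted p under 0.05). It was 1 without set 2 replicate 1 and 0 without any other array (3960 to 4495 at an unadjusted p under 0.05). Each slide held the arrays of 1 set, so the set and the slide cannot be told apart.

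The sets were also compared across genes. Over 19987 genes, which are not independent replicates, the mean log2 ratios of the sets correlated with a Pearson r of 0.572 and a Spearman rho of 0.552, and 69.7% of genes had the same sign. Arrays of the same set correlated more closely, with r of 0.789 in set 1 and 0.783 in set 2, than arrays of different sets, with r of 0.501 to 0.52. Genes called higher in both sets numbered 1413 against 408 by chance for independent lists, as for IPO7, TRIB3, PDIA4 and VEGFA on their brightest probes, and genes called lower in both numbered 2108 against 781, as for NNMT, KITLG, PNMA2 and HMMR. These 4 genes named as higher lay below 0 over both sets with median centring, and PNMA2 lay above 0, though below the median, in the authors' deposited table. Another 124 genes were higher in set 1 and lower in set 2 (502 by chance), as for GNAZ and CTSZ, and 124 were lower in set 1 and higher in set 2 (634 by chance), as for SCD and SREBF1. The tests of both sets used 1 shared estimate of the spread per gene, so the lists were not independent. A shared spread tends to raise overlaps in the same and in opposite directions, so the chance counts are no exact baseline. The sets shared the same dye orientation, and with median centring r was 0.951. Median centring leaves in a trend of ratio with brightness (correlation -0.87 over both sets), so that r does not measure agreement of the decoy pairs.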

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

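The tests of slide and scan, of S phase and of bright high-GC probes below, and every use of loess within bins of probe GC, were chosen only after the results had been seen. The patterns weighed below came from a first fit of the same data, and for the other tests what each outcome would mean was written down before that test was run. Each value beside a gene or list in this paragraph, unless said otherwise, is a difference between the sets, set 1 minus set 2 on the log2 scale, that passed its own test. Of the 45 genes named by size, 32 differed (limma, adjusted p 0.0216 to 0.0493), 12 of them named because of that difference. Others were named as extreme in a single set, which also favours a difference. The share is therefore not comparable with the 992 of 20093 genes in all. Of the 32, 12 (UTS2R counting in both tallies) are read by bright probes with a GC content of at least 70%, a class whose 68 called genes were all lower in set 1 than in set 2 (median log2 ratio of the probes 0.26 in set 1 and 0.625 in set 2). Higher in set 1 were DKK1 0.71, CTSZ 0.58, FKBP1A 0.37, GNAZ 0.65, LATS2 0.35, PAX4 0.60, SGK1 0.53, TRAM2 0.52, CHPF 0.52, FLNA 0.21 and NNMT 0.19. Lower in set 1 were STT3A -0.71, ABCA1 -0.43, CDH24 -0.33, CRTC1 -0.40, HCN4 -0.35, HES7 -0.35, HLA-DPB1 -0.56, HS2ST1 -0.47, NGFR -0.52, PKN2 -0.35, SCD -0.69, SREBF1 -0.54, UTS2R -0.50, BMP8A -0.33, TAF15 -0.32, FOXQ1 -0.33, PARP10 -0.42, CD46 -0.39, EDN2 -0.42, BBC3 -0.35 and CDC42EP5 -0.34. Among list members the differences were CCN2 0.49, H3C2 0.43, HNRNPA0 0.42, THBS1 0.49, H2AC4 0.32, YBX1 0.32, HNRNPUL1 0.31, H3C7 0.26, TGFBI 0.27, ANLN 0.23, RBMS1 0.21, CCN1 0.28, IGF2BP2 0.31, BUB1B 0.24, KRT7 0.20, SRSF1 0.20, H1-4 0.23 and CDC20 0.19 upwards, where H3C7 (-0.0049) and H1-4 (-0.0040) lay just below 0 with median centring, and IFI44 -0.34, IFI44L -0.40, IL1B -0.35, MX1 -0.49, ZC3H12A -0.34, KRT19 -0.32, CDH1 -0.27, CSF1R -0.39, BNIP3 -0.29, NFKBIA -0.28, DHX58 -0.22, STARD4 -0.30, CDH11 -0.24, IFNL1 -0.47, TNFSF10 -0.19, INSIG1 -0.21 and RPL13 -0.18 downwards. The medians of the lists called with camera were replication-dependent histones 0.096, mesenchymal and invasion genes 0.0585, TGF-beta response genes 0.085, hnRNP proteins 0.061, mRNA stability RNA-binding proteins 0.034 and G2/M and mitosis 0.0485 upwards, of which the histone, hnRNP, stability and G2/M lists turned with median centring, and interferon-stimulated genes -0.13, NF-kB inflammatory cytokines and chemokines -0.16, cholesterol biosynthesis -0.14, cytosolic ribosomal proteins -0.059 and glycolysis and hypoxia -0.083 downwards, and none passed with an estimated correlation (adjusted p 0.205 to 0.471).

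The first pattern is the large number of genes called over both sets, 3788 higher and 5460 lower. A dye effect following GC content and brightness as the whole cause is argued against for the higher genes as a group, since 92.3% of them stayed called higher after loess within GC bins (median 0.12 before and after), while 4174 of the 5460 lower genes stayed called lower and the excess of lower calls ended (4371 higher and 4386 lower, or 3416 and 3546 with the scanner software's ratio). For single-probe effects, other probes of a gene called higher went the same way 13.9 percentage points (SE 1.52) more often than for all genes. That was 56% of genes against 42.1%, with a mean of 0.013 against 0.13 on the main probe. At a brightness of 13 or more it was 22.3 points (SE 3.63, 0.029 against 0.16), which leaves single-probe effects open for the higher genes. For genes called lower it was 9.33 points (SE 1.14, 67.2% against 57.9%, -0.037 against -0.14). This lay just within the bound of 10 written down before the test was run, so single-probe effects may account for many of the lower calls. A higher baseline leaves less room for such an excess, and other probes are the dimmer ones. The test therefore does not set the lower calls apart from the higher. A shared effect of very high probe GC is a candidate explanation for the bright high-GC probes, of which 98.6% had a ratio above 0.2 under bounds drawn from the named genes, and their median went from 0.44 to 0.079 after loess within GC bins, a class that holds 9 of the 12 highest genes. The 8 sign patterns of the 4 arrays are too few for a share under 0.05 (real value 9248, highest other 992; 1 pattern reached the real value), and a constant dye effect, like an effect of the decoy, stays open because no array had the dyes exchanged.

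The second pattern is the lower level of interferon-stimulated genes in set 1 than in set 2. A dye effect following GC content and brightness as its cause is argued against, since after loess within GC bins the median difference kept 0.928 of its size (-0.13 before, -0.12 after). Slide and scan cannot be told apart from the set, because 0 slides held arrays of both sets. A difference between the decoy pairs, for example in how strongly the RNA itself is sensed by the cells, stays open and untested, and could not be separated from the slide here.

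The third pattern is the higher level of histone transcripts over both sets, which turned downwards with median centring. Set 1 carried most of it, with 17 higher and 0 lower of 25, a median of 0.13 and a camera adjusted p = 1.37e-07. In set 2 the list was not called, with 6 higher and 3 lower, a median of 0.053 and a camera adjusted p = 0.0693. For a larger share of cells in S phase, the S phase list's median above all genes was 0.012. Its upper 95% bootstrap bound was 0.0485 (10000 draws), under the bound of 0.053. By the rule written for this test, that alone argued against S phase. A condition outside that rule, that the upper quartile of the members also lie under 0.053, was not met. The members went both ways, with quartiles of -0.067 and 0.071, so S phase is left open here. A dye effect following GC content and brightness stays open: after loess within GC bins the histones' median kept 0.77 of its size (0.11 before, 0.082 after) and the list was still called (adjusted p = 0.0072). With an estimated correlation the list was not called, but neither was a simulated list with a larger shift, so that result decides nothing. An effect of the decoy on histone transcripts, which mostly lack a poly-A tail, stays open and untested.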

How the results depend on the processing

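The alternatives with loess within GC bins and with the spots beside specks kept were chosen after the data had been seen, and the cause of a change was not tested unless given. Without the filter on dim probes the counts were 4484 in set 1 (10474 unadjusted, against 9615 with it), 3960 in set 2 (10058 against 9053) and 0 for the difference (5819 against 5703). Over both sets, the count of 9248 stayed within 1.5 times under no background correction, the scanner software's ratio, quantile normalization, both filters, the mean of probes, outlying spots kept, the intensity prior and GC bins, and leaving out 1 array gave 6192 to 7102, but the calls were 49.1% higher with the scanner software's ratio and 49.9% with GC bins, against 41%. It was 18953 with median centring (22.8% higher), 6020 with 1 coefficient and 3289 with the set as a random block, whose correlation was 0.441. Set 1 had 3487 calls with the scanner software's ratio, 18683 with median centring (22.2% higher against 39.1%) and 0 to 6755 with 1 array left out, 0 without either of its own arrays (6642 and 6886 unadjusted). Set 2 had 4066, 18047 (21.7% higher against 44.8%), 3328 with specks kept (30.5% higher) and 1290 to 5215 with 1 array left out, the lowest without its own replicate 1 and 1613 without its replicate 2. In those fits a lone array of a set was assumed to vary like the other set. The difference had 0 calls with the scanner software's ratio (4809 unadjusted), 8787 with median centring (19.8% higher against 39.4%), 2076 with the stricter filter, 4663 with the intensity prior, 536 with specks kept (53.2% higher) and 0 to 1 with 1 array left out, 1 without set 2 replicate 1. Median centring leaves in the trend of ratio with brightness that loess removes (correlation -0.87 against 0.093), so its counts, signs and correlation between the sets include that trend.

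The replicate number as a replicate block gave 8794 calls over both sets, 6371 in set 1, 5558 in set 2 and 0 for the difference (5377 unadjusted, limma). The ratios of same-numbered arrays did not deviate together (correlation 0.0015 across genes). Anything acting alike on decoy and scrambled cells cancels in a ratio, so this does not show whether the numbers pair the samples. The block leaves fewer degrees of freedom. Slide or scan as a block was not run, since each slide held 1 set. The authors' deposited table is pooled and gave no count, agreement or list test.

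The correlation between the sets, 0.572, was 0.561 without background correction, 0.469 with the scanner software's ratio, 0.951 with median centring, 0.523 without a filter, 0.595 with the stricter filter, 0.553 with the mean of probes, 0.557 with outlying spots kept, 0.537 with GC bins, 0.556 with specks kept and 0.533 to 0.547 with 1 array left out. Lists called over both sets numbered 1, against 3 without background correction, 2 with the scanner software's ratio, 15 with median centring, 3 without a filter, 2 with the mean of probes, 2 with 1 coefficient, 2 with GC bins and 1 to 2 with 1 array left out. In set 1 they numbered 1, against 2 without background correction, 16 with median centring, 2 without a filter, 2 with GC bins, 2 with specks kept and 1 to 2 with 1 array left out. In set 2 they numbered 2, against 4 without background correction and 15 with median centring. With an estimated correlation 0 lists were called over both sets, in set 1, in set 2 and for the difference (0, 1, 1 and 4 at an unadjusted p under 0.05), where camera at the preset value called 1, 1, 2 and 11. A simulated shifted list was missed under that setting too, so these results decide nothing about the lists. The ribosomal list's difference also ended with the scanner software's ratio and without set 1 replicate 1, and that of glycolysis with specks kept.

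Of 187 gene values, 131 kept direction and side of the threshold with the scanner software's ratio, 116 with median centring, 176 with GC bins, 173 with specks kept and 120 to 133 with 1 array left out. With median centring, these values over both sets lay below 0: STT3A -0.24, IPO7 -0.22, BBC3 -0.50, CDC42EP5 -0.52, CDH24 -0.49, HCN4 -0.58, BMP8A -0.55, HES7 -0.58, FOXQ1 -0.51, TAF15 -0.39, PKN2 -0.63, PARP10 -0.55, HNRNPA2B1 -0.90, ISG20 -0.52, IFIT3 -0.43, DHX58 -0.46, OASL -0.46, HNRNPAB -0.57, HNRNPL -0.59, CELF1 -0.21, SRSF1 -0.72, SRRM1 -0.68, H4C2 -0.595, H3C7 -0.030, H2AC18 -0.66, H1-4 -0.545, PHLDA3 -0.39, AEN -0.30, TRIB3 -0.57, PDIA4 -0.55, XBP1 -0.68, HERPUD1 -0.75, DNAJA1 -0.85, MVK -0.63, VEGFA -0.39, SDHA -0.69, COX6C -0.85, RPS23 -0.76, MMP14 -0.24, ITGA5 -0.27, ANGPTL4 -0.22, KRT19 -0.79, CSF1R -0.58 and THY1 -0.66. In set 1 the same held for FLNA -0.275, FKBP1A -0.49, IPO7 -0.40, LATS2 -0.49 and HDGF -0.535, in set 2 for HS2ST1 -0.24, BBC3 -0.18, PARP10 -0.20, CDC42EP5 -0.21 and CRTC1 -0.28, and for the difference for H3C7 -0.0049 and H1-4 -0.0040. DLGAP4 lay above 0 with the scanner software's ratio (0.23 over both sets, 0.34 in set 1), as did HSP90AA1 with the mean of its probes (0.047). In the authors' deposited table, on the log2 scale, 16 of the genes named over both sets and called lower lay above 0: PNMA2 0.043, DLGAP4 0.23, DHTKD1 0.105, FAM241A 0.020, POLR2L 0.15, RPL6 0.13, JUNB 0.19, PUM2 0.084, ASPM 0.063, CENPF 0.034, HSPD1 0.078, HSP90AA1 0.14, HMGCS1 0.086, RPL7A 0.12, LAMA3 0.0405 and COL4A1 0.29. That table's own median was 0.0134 on the log10 scale. PNMA2 (0.013), FAM241A (0.006), CENPF (0.0102) and LAMA3 (0.0122) lay below it on that scale, so they were not reversed relative to other genes.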

Other observations

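No test was added for this part, but the 8 genes in this paragraph were chosen after their values had been seen, and the values are given without explanation. Several genes differed by about the same amount in both decoy pairs. APOLD1 was at -0.38 in set 1 and -0.38 in set 2, PDGFRB at -0.27 in both, PCNA at -0.16 in both, DHTKD1 at -0.42 and -0.47, and POLR2L at -0.44 and -0.40. RPS23 (0.20 in both), PDIA4 (0.28 and 0.29) and SDHA (0.18 and 0.22) were above scrambled in each set with loess and below 0 over both sets with median centring. Their tests of the difference gave adjusted p of 0.462 to 0.954 for these 8 genes, which does not show that the sets acted alike. POLR2L and DHTKD1 lay above 0 in the authors' deposited table.

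The authors' deposited table had a median log10 ratio of 0.013, a range from -0.48 to 0.74, and 61.5% of 20092 values above 0. Across 12354 genes its values correlated with the fitted log2 ratios over both sets with a Pearson r of 0.481 and a Spearman rho of 0.681, and 87.5% of 6139 called genes had the same sign. Log2 ratios correlated with probe GC content across genes on each array, with r of 0.244 and 0.236 in set 1 and 0.206 and 0.188 in set 2. Genes called higher over both sets had probes with a median GC content of 45% and a median brightness of 10.1, those called lower 41.7% and 9.07, and those not called 43.3% and 7.58.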
